A study of Homo sapiens with 6 samples.

How the data were processed

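RNA abundance was measured by RNA sequencing in 6 libraries of the MHCC-97H line, 3 treated with DMSO and 3 with 2 µM GK921 for 24 h. Per the labels' protocols, total RNA was isolated with Trizol and libraries followed standard Illumina protocols. Whether poly(A) RNA was selected, ribosomal RNA depleted or the strand kept is not given in the sources used here. The submitters' processing notes name FastQC 0.11.5, HISAT2, featureCounts, edgeR and the build hg38, without versions for the other tools and without saying which step each served. The gene annotation is not given in the sources used here. Values were deposited as FPKM per gene symbol and library with 2 decimals, per the file headers. FPKM is relative to the fragments assigned in each library, so a change of RNA content per cell is not visible in it. The values of a library summed to between 821498 and 836182. These sums cannot tell FPKM from TPM, a similar unit scaled to a fixed total, so the unit rests on the headers.

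Groups and replicate numbers came from the sample titles and treatment labels. Read totals are not given in the sources used here, so absolute depth is unknown and no counting intervals could be set. Relative depth was estimated from genes with low FPKM, where one fragment makes a visible step. All 15 pairs of libraries lay within 0.05 log2 units of a joint fit, from 27 to 134 genes a pair, on the assumptions that the values are FPKM and that a gene's length was the same in each library. The same procedure recovered the depth of simulated libraries within 0.08%. Those libraries had fixed gene lengths and counting noise only, as the method assumes, so this error need not hold for the data. By the estimate from the deposited values, the DMSO libraries were on the whole deeper, so values near 0 are coarser after GK921. Within a group, at most 0.389% of tested genes had identical values in 2 libraries, and each library was counted as its own replicate.

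Values were used as deposited. They were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 6 libraries, with treatment as the only term, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called higher or lower. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and printed folds are ratios of mean FPKM. Lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and with fry beside it. Some genes are on more than 1 list, so the lists are not independent. The 39 lists of textbook genes were written before the data were examined, as were the tests, the alternatives and the rule for named genes. That rule took TGM2 and MYC, and the 12 largest rises and falls among called genes with separate groups and a mean of at least 5 FPKM in the higher group. It also took up to 4 called members of each list by size of change, with at least 1 of each direction. Where no member was called it took up to 2 of the most abundant, and for lists with fewer than 5 tested members the 3 most abundant. The examples in the text are drawn from those genes, some of which are not reported here. Counts are adjusted over all tested genes, and those adjusted over the list alone are given where they differed. TGM2 and MYC were also compared by an exact permutation test, whose p cannot fall below 0.1.

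The pipeline was tested on simulated data with known changes in the comparison of GK921 with DMSO, with 50 genes per fold size among 11334. It recovered 66% of genes changed 1.2-fold, 86% of those changed 1.5-fold, 94% of those changed 2-fold and 98% of those changed 4-fold, and 3.37% of its calls were false. When the mitosis list was also lowered 2-fold in these simulated libraries, 1 list was called. The simulation drew noise independently for each gene, changed few genes and had no shift between the groups. The data differ in each of these, so these rates need not hold for them.

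Alternatives were the pseudocount, the expression limit, 4 rescalings of the libraries, the replicate number as a block, each library left out in turn, no intensity trend, array weights, a test against a 1.2-fold change (treat), the estimated correlation and fry. A correction for transcript GC content and length, its combination with the block, a rescaling without the 100 most abundant genes, and a shortened list of MYC targets were added after seeing the data. Positions, GC content and lengths came from GENCODE release 29 (GRCh38), in which 20255 symbols were matched, and which gave GC content and length for 99.4% of tested genes. Its release need not be the one behind the deposited values. Genes with near-identical copies (histones, ribosomal proteins and their pseudogenes, HSPA1A and HSPA1B, UGT1A, AKR1C, tubulins, metallothioneins) and genes that overlap on opposite strands are uncertain, since the handling of shared reads and strand is not given in the sources used here. A count model was not used because the values are FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.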

Results

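The series holds 6 libraries of total RNA from MHCC-97H, an established human hepatocellular carcinoma cell line with high metastatic potential. 3 libraries came from cells given the solvent DMSO and 3 from cells given 2 µM GK921, an inhibitor of transglutaminase 2 (TGM2), for 24 h. TGM2 cross-links proteins and can attach serotonin to glutamine residues, histone H3 included. The series title names TGM2, histone serotonylation and MYC signalling, so the comparison asks how the transcriptome of these cells differed after exposure to the inhibitor. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped total) for 20388 gene symbols, of which 4446 were listed at 0 in every library. Read totals are not given in the sources used here. From the steps between low FPKM values, the depths relative to the deepest library were 1, 0.942 and 0.869 in DMSO, against 0.767, 0.771 and 0.863 after GK921. Between 13992 and 14433 genes were above 0 in a library. Libraries of one group correlated at r = 0.993 to 0.995 across genes and libraries of different groups at 0.914. The median coefficient of variation of a tested gene was 5.63% in DMSO and 6.01% after GK921. No source states that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

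Most tested genes differed between the groups, and most of these differences were under 2-fold. Genes of mitosis, DNA replication and WNT signalling mostly fell, and genes of the unfolded protein response, the amino acid stress response and replication-dependent histones mostly rose. Of 11573 genes with a mean of at least 1 FPKM, 5411 (46.8%) were higher and 3378 (29.2%) lower at a limma adjusted p under 0.05. The change reached 2-fold on the log2(FPKM + 1) scale for 1864 of them, 1142 higher and 722 lower. That count depended on the pseudocount, at 1064 with a pseudocount of 5 and 2328 with one of 0.1. A test against a 1.2-fold change (treat) called 5730 genes (49.5%). The values of the groups did not overlap for 9026 genes (78%), where chance gives 10%. The first principal component held 91.7% of the variance. The median tested gene was 0.16 higher on the log2 scale, and the split between rises and falls depended on this shift. With libraries rescaled by median ratios, which brought the median change to 0.0049, 4258 genes were higher and 4317 lower, so the share of calls that were rises went from 61.6% to 49.7%. With quantile normalization that share was 51.9% (4387 higher and 4071 lower). Measured from the median change, 824 called genes lay more than 1 log2 unit above it and 946 more than 1 below. All fold changes below are on the scale of the deposited values, and subtracting 0.16 from a log2 change gives it relative to the median gene.

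**Figure D1:**
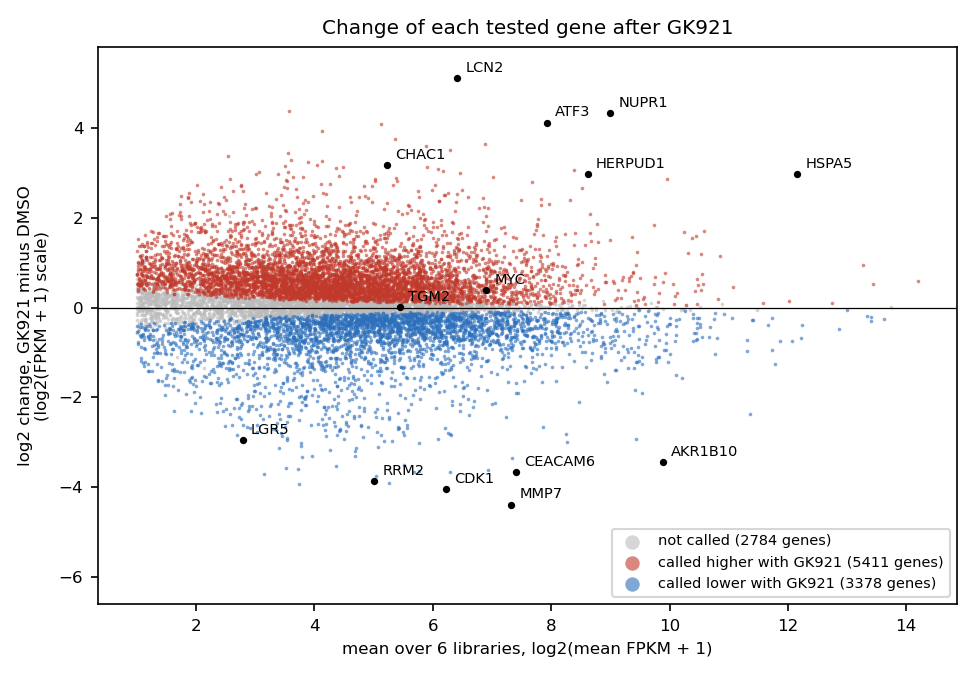
Each point is one of the 11573 tested genes, with the log2 of its mean FPKM plus 1 over the 6 libraries on the x axis and its log2 change, GK921 minus DMSO, on the y axis. Red points were called higher (5411 genes) and blue points lower (3378 genes), with TGM2 at 0.017 and MYC at 0.39. The split between red and blue moved to 4258 and 4317 with median-ratio scaling.

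TGM2 itself (chromosome 20, 38127387 to 38166578 in GRCh38) did not differ in mRNA level between the groups by the limma test. Its mean was 42.1 ± 0.0265 FPKM in DMSO and 42.6 ± 0.345 FPKM after GK921 (SD, n = 3 libraries per group, as for every mean below). The log2 change was 0.017 ± 0.040 (SE), with a limma adjusted p of 0.71. With median-ratio scaling it was -0.15 and called lower (limma adjusted p = 0.00878). As deposited, its 3 GK921 values (42.2 to 42.9 FPKM) all lay just above its 3 DMSO values. No other gene of the 9-member transglutaminase list reached the expression limit. MYC (chromosome 8, 127735434 to 127741434), the transcription factor that drives ribosome production and proliferation, rose 1.31-fold from 103 ± 4.82 to 135 ± 1.43 FPKM. Its log2 change was 0.39 ± 0.040 (limma adjusted p = 2.10e-05), or 0.23 above the median gene, and it was called higher under each of the 5 rescalings, at 0.22 to 0.40. The exact two-sided permutation p was 0.1 for each of the 2 genes, the smallest that 3 against 3 allow.

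**Figure D2:**
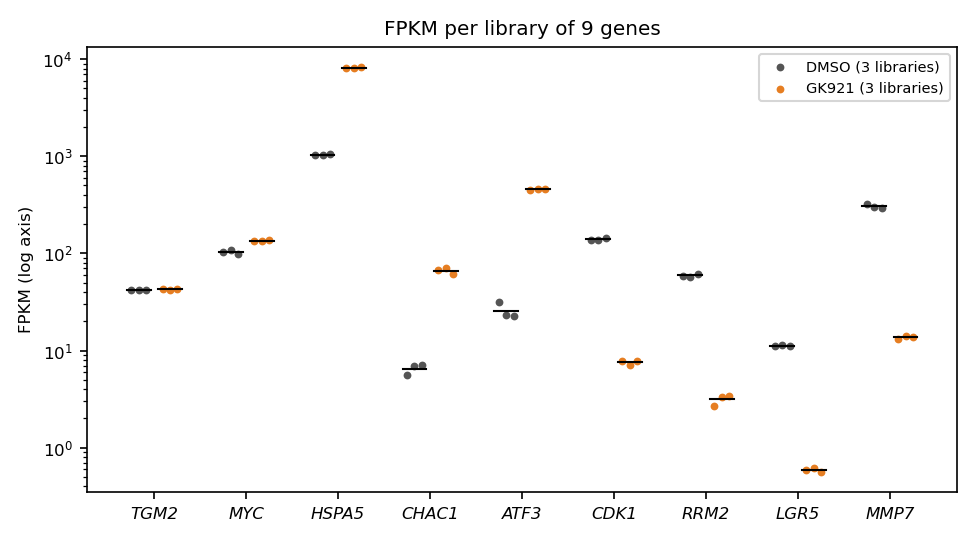
FPKM of 9 genes in each library on a log axis, with grey points for the 3 DMSO libraries, orange points for the 3 GK921 libraries and a black line at each group mean. The groups lie close together for TGM2 (42.1 and 42.6 FPKM), and far apart for HSPA5 (1038 and 8127) and CDK1 (140.2 and 7.55).

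The largest rise on the log2(FPKM + 1) scale was that of LCN2, the secreted iron-siderophore carrier lipocalin 2, from 3.93 ± 1.48 to 164 ± 2.79 FPKM (41.8-fold, log2 change 5.11 ± 0.18, limma adjusted p = 2.09e-08). The stress-induced transcription regulators NUPR1 and ATF3 rose 20.4-fold to 972 ± 22.7 FPKM and 17.8-fold to 459 ± 5.28 FPKM. INHBE, which encodes a subunit of activin E, rose from 1.17 ± 0.405 to 31.9 ± 0.697 FPKM, and the cytokine receptor chain IL20RB rose 22.4-fold. The neuropeptide gene SPX rose 13.2-fold and the nuclear envelope gene SUN3 16.1-fold. The adaptor gene SH2D3C went from 0.0867 ± 0.0462 to 21.6 ± 1.68 FPKM, a larger ratio of means (249) from a value near 0, and the muscle ring-finger gene TRIM55 from 0.953 ± 0.0416 to 20.5 ± 3.33. MYOZ2, a gene of the sarcomere, was listed at 0 in the 3 DMSO libraries and at 12.5, 8.41 and 7.89 FPKM after GK921. The largest fall on the log2(FPKM + 1) scale was that of the matrix metalloproteinase gene MMP7, from 306 ± 12.5 to 13.7 ± 0.574 FPKM (22.4-fold lower, log2 change -4.39 ± 0.047, limma adjusted p = 5.76e-11). The cell adhesion gene CEACAM6 was 13.2-fold lower and ASB4, an adaptor of ubiquitin ligases, was 60.4-fold lower. The replication-linked protease gene FAM111B was 37.8-fold lower, the transcription factor gene MYBL2 14.3-fold and the mitotic kinase gene PBK 14-fold.

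Genes of cell division fell together. All 43 tested mitosis genes were called lower, with a median log2 change of -2.45 (camera adjusted p = 4.00e-24). CDK1, the kinase that drives entry into mitosis, fell from 140.2 ± 5.01 to 7.55 ± 0.459 FPKM (18.6-fold), TOP2A, which untangles sister chromatids, fell 13.8-fold, the ubiquitin-conjugating enzyme gene UBE2C 12.8-fold and CDCA3 18.6-fold. Of 41 DNA replication genes, 40 fell and 1 rose, with a median of -1.77 (camera adjusted p = 8.25e-18). The helicase assembly gene GINS2 was 16.8-fold lower, MCM10 23-fold and UHRF1, which maintains DNA methylation, 14.5-fold. The exception was cyclin E1, CCNE1, at a log2 change of 0.24 ± 0.067, a call that was lost with median-ratio, upper-quartile and quantile scaling. Of 27 nucleotide synthesis genes, 24 fell and 3 rose (median -0.80, camera adjusted p = 1.07e-07). The deoxynucleotide enzymes RRM2 and TK1 fell 18.9-fold and 7.52-fold, while the mitochondrial folate enzyme MTHFD1L rose 2.12-fold. These 3 lists were also called with an estimated correlation, at camera adjusted p-values of 0.00824, 0.023 and 0.023.

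Most textbook MYC targets fell although MYC mRNA rose. Of 56 tested targets, 45 were lower, 3 higher (4 adjusted over the list alone) and 8 not called, with a median log2 change of -0.48 (camera adjusted p = 6.88e-12, or 0.0294 with an estimated correlation). The replication helicase genes MCM4 and MCM5 and the mitotic kinase gene PLK1 fell 7.21-fold, 5.46-fold and 7.05-fold. MCM4 and MCM5 are also on the replication list and PLK1 on the mitosis list, so their falls are not typical of the targets. The 52 targets on none of the mitosis, replication and nucleotide lists had a median log2 change of -0.47. The mitochondrial RNA helicase gene SUPV3L1 rose 1.95-fold. Of 58 ribosome biogenesis genes, 38 fell and 5 rose (median -0.25, camera adjusted p = 2.79e-06, or 0.023 with an estimated correlation). Among them BOP1, PWP2 and NAT10, which process or modify ribosomal RNA, fell 1.96-fold, 2.09-fold and 1.81-fold, and TAF1D, part of the RNA polymerase I initiation factor, rose 2.2-fold. Of 71 ribosomal protein genes, 46 fell and 14 rose (median -0.23, camera adjusted p = 1.46e-05, or 0.415 with an estimated correlation of 0.411). With quantile normalization 34 fell and 25 rose, and that list was no longer called. RPS26 was 2.52-fold lower and RPL7A 2.32-fold, with RPS12 1.48-fold higher, and pseudogenes of this family may share their reads. In the network of MYC, MAX and their partners, 9 of 11 tested genes rose and 1 fell (median 0.69), and the list missed the threshold (camera adjusted p = 0.0515, or 0.15 with an estimated correlation). It was called higher in 10 of 20 camera alternatives with the preset correlation. These included median-ratio scaling (camera adjusted p = 0.0343), a mean of at least 5 FPKM (0.0241) and the fits without the second DMSO library (0.0494) or the second GK921 library (0.0411). MXI1 and MXD4, which compete with MYC for MAX, rose 2.41-fold and 2.07-fold, MYCL went from 0.42 ± 0.0854 to 1.84 ± 0.468 FPKM, and MXD3 fell 2.03-fold.

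**Figure D3:**
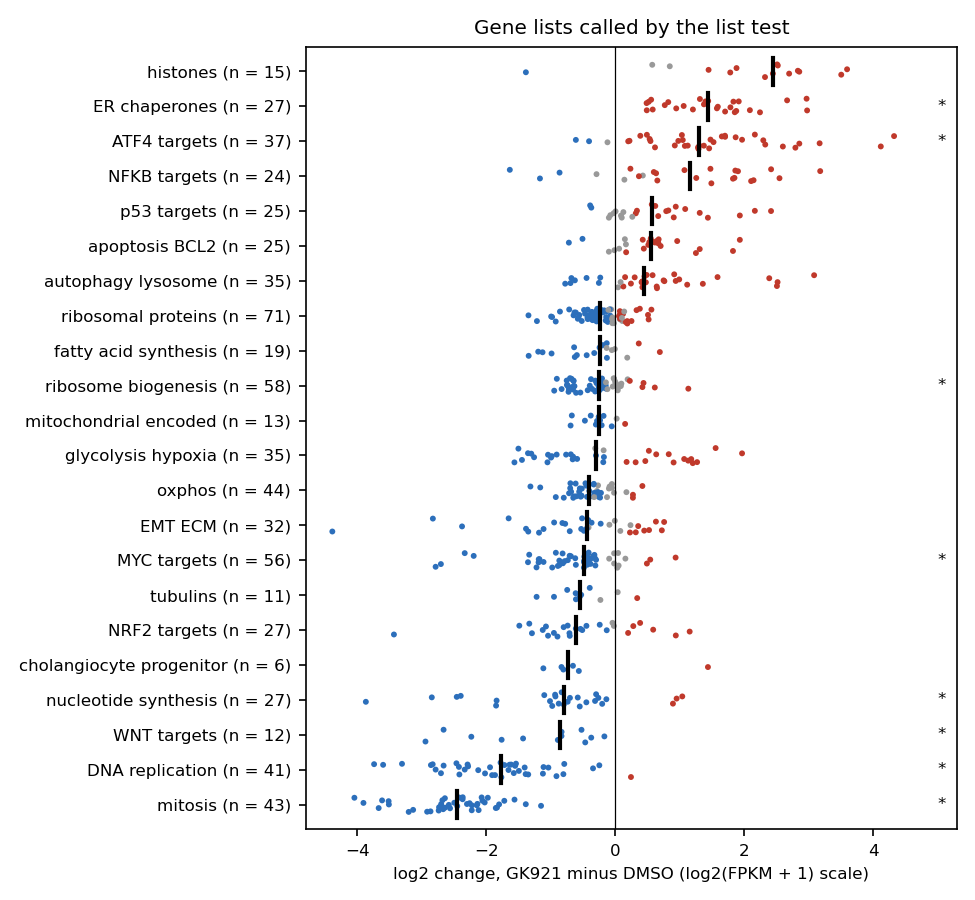
Log2 change, GK921 minus DMSO, of each tested member of the 22 lists called by camera, with red for called higher, blue for called lower, grey for not called and a black bar at the list median (vertical jitter only separates points). Medians run from -2.45 for mitosis to 2.44 for histones. Asterisks mark the 8 lists also called with an estimated correlation, and quantile normalization ended the calls of the ribosomal protein, mitochondrially encoded and glycolysis lists.

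Endoplasmic reticulum stress genes rose together. All 27 tested genes of the unfolded protein response list were higher, with a median log2 change of 1.44 (camera adjusted p = 2.70e-09, or 0.023 with an estimated correlation). HSPA5 (chromosome 9, 125234853 to 125241330), the main luminal chaperone BiP, rose 7.83-fold from 1038 ± 13.3 to 8127 ± 113 FPKM. HERPUD1, which acts in the degradation of misfolded proteins, rose 7.94-fold, and the co-chaperone genes DNAJB9 and SDF2L1 6.39-fold and 4.81-fold. Of 37 genes driven by ATF4, the transcription factor of the integrated stress response, 34 rose and 2 fell (median 1.30, camera adjusted p = 1.07e-07, or 0.023 with an estimated correlation). Besides NUPR1 and ATF3, the glutathione-degrading enzyme gene CHAC1 rose 10.2-fold, while SLC7A11, the cystine transporter, fell 1.53-fold. Of 19 heat shock genes, 7 rose and 11 fell, with no call for the list (camera adjusted p = 0.252). HSPA1A and HSPA1B, near-identical genes whose reads cannot be told apart with certainty, were listed 2.43-fold and 2.28-fold higher, DNAJB1 rose 2.29-fold and the mitochondrial co-chaperone gene HSPE1 fell 1.86-fold.

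Genes of cell death, lysosomes and inflammation mostly rose, in lists called with the preset correlation only. Of 25 p53 targets, 15 rose and 2 fell (median 0.57, camera adjusted p = 0.0302, or 0.123 with an estimated correlation). The growth arrest genes GADD45A and SESN2 rose 5.4-fold and 4.68-fold, the BH3-only gene BBC3 rose 4.15-fold and the nuclease gene AEN fell 1.32-fold. The p53 list lost its call without the third GK921 library (camera adjusted p = 0.0503). Of 25 BCL2 family and death genes, 18 rose and 2 fell (3 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.0168, or 0.0965 with an estimated correlation). The death receptor gene TNFRSF10B rose 2.5-fold, the caspase inhibitor gene BIRC3 3.71-fold, and CASP6 fell 1.68-fold. Among these named genes, BBC3 and TNFRSF10B are on both the p53 and the death gene list. SESN2 is also on the ATF4 list, and BIRC3 is also on the list of NF-kappaB targets described below. These rises are therefore not separate evidence for each list. Of 35 autophagy and lysosome genes, 26 rose and 7 fell (median 0.45, camera adjusted p = 0.0168, or 0.0965 with an estimated correlation). The proton pump subunit gene ATP6V0D2 rose 9.01-fold, the autophagosome genes GABARAPL1 and WIPI1 5.88-fold and 5.9-fold, and the lysosomal protease gene CTSA fell 1.72-fold. Of 24 NF-kappaB targets, 18 rose and 3 fell (median 1.16, camera adjusted p = 0.00185, or 0.0664 with an estimated correlation). The cytokine gene IL1A rose 12.5-fold and the chemokine gene CXCL2 6.92-fold, whereas CXCL8, another neutrophil chemokine, fell 3.55-fold.

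Interferon-stimulated genes moved both ways, with 17 of 27 higher and 6 lower and no call for the list (camera adjusted p = 0.133). IFIT2 rose from 0.787 ± 0.316 to 10.8 ± 0.265 FPKM and IFI35 and ISG20 5.36-fold and 4.43-fold, while OAS3, a sensor of double-stranded RNA, fell 6.63-fold. Of 30 immediate early genes, 17 rose and 8 fell (camera adjusted p = 0.391). The phosphatase gene DUSP1 rose 7.17-fold and KLF4 3.16-fold, and the transcription factor gene EGR1 fell 4.08-fold. Of the 4 metal-response genes tested, 3 rose (4 adjusted over the list alone). These included MT2A (3.46-fold) and MT1X (3.42-fold), which belong to a family of similar sequences, and the zinc exporter gene SLC30A1 was at 39.2 ± 0.52 and 42.4 ± 1.48 FPKM (limma adjusted p = 0.0516).

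Replication-dependent histone genes, which supply nucleosomes in S phase, went against the replication genes. Of 15 tested, 12 rose (13 adjusted over the list alone) and 1 fell, with a median log2 change of 2.44 (camera adjusted p = 0.00369, or 0.123 with an estimated correlation). H2BC21 rose 13.4-fold to 108 ± 10.8 FPKM, H2AC6 12.1-fold to 143 ± 10.6 FPKM and H2BC4 8.05-fold, and H2AC20 fell from 3.34 ± 0.378 to 0.687 ± 0.369 FPKM. Replication-dependent histone genes are similar in sequence, and mature transcripts of most lack a poly(A) tail. H2BC21, H2AC6 and H2BC4, however, are among 5 genes known to give polyadenylated transcripts in non-dividing cells, a list written after values had been seen. In a wider set of 29 such histone genes, the median log2 change was 2.85 for those 5 and 1.96 for the others. Of 11 tubulin genes, 8 fell and 1 rose (median -0.55, camera adjusted p = 0.00151, or 0.0664 with an estimated correlation). TUBB and TUBA1B, a beta and an alpha tubulin gene, fell 2.33-fold and 1.93-fold, and TUBB6 was 1.29-fold higher, a call lost with median-ratio and quantile scaling. Of 24 listed genes linked to histone H3 lysine 4 methylation, general transcription factor genes such as TBP included, 12 were higher and 6 lower (camera adjusted p = 0.88). With median-ratio scaling 7 were higher and 9 lower. WDR5, a shared subunit of the methyltransferase complexes, fell 1.46-fold, the demethylase gene KDM1A fell 1.54-fold and KDM5B rose 1.66-fold. Of 7 tested genes of serotonin handling, 3 fell and 1 rose, the rise not called when adjusted over the list alone, with no call for the list (camera adjusted p = 0.142). MAOB, which encodes a monoamine-degrading enzyme, fell 3.47-fold, and DDC, whose enzyme makes serotonin, 1.72-fold. The receptor gene HTR1D was at 4.17 ± 1.07 and 5.68 ± 0.699 FPKM, a rise (limma adjusted p = 0.0459) that was not called with median-ratio, upper-quartile or quantile scaling. Without the first or the third DMSO library, or the second or the third GK921 library, it was not called either (limma adjusted p = 0.117, 0.154, 0.0802 and 0.146).

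Among metabolic genes, targets of the antioxidant factor NRF2 mostly fell. Of 27 tested, 19 were lower and 6 higher (median -0.61, camera adjusted p = 2.88e-05, or 0.0664 with an estimated correlation). The aldo-keto reductase gene AKR1B10 fell from 1729 ± 98.2 to 159 ± 1.45 FPKM (10.9-fold) and AKR1C3, of a family of close paralogs, 2.81-fold, while PIR rose 2.28-fold. Of 44 nuclear genes of the respiratory chain, 31 fell and 3 rose (median -0.41, camera adjusted p = 6.49e-08, or 0.0683 with an estimated correlation). The ATP synthase genes ATP5MC3 and ATP5F1B fell 2.5-fold and 1.9-fold, and COX5B rose 1.34-fold. Of 13 mitochondrially encoded transcripts, 11 fell and 1 rose (median -0.26, camera adjusted p = 0.0026, or 0.393 with an estimated correlation of 0.621). MT-ND6 and MT-ND5 fell 1.62-fold and 1.6-fold, while MT-ND1 was 1.11-fold higher as deposited and at -0.014 on the log2 scale with median ratios. Under quantile normalization 8 fell and 3 rose, and the list was not called. The list of glycolysis and hypoxia genes went both ways, with 19 lower (20 adjusted over the list alone) and 14 higher of 35 (median -0.30). Its camera adjusted p was 0.0302, or 0.108 with an estimated correlation, and median-ratio, upper-quartile and quantile scaling ended the call, as did a mean of at least 5 FPKM (0.0599). The pyruvate kinase gene PKM fell 2.84-fold, and the hypoxia targets VEGFA and BNIP3L rose 4.02-fold and 2.99-fold while CA9 fell from 3.18 ± 0.762 to 0.42 ± 0.318 FPKM. VEGFA is also on the ATF4 list.

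Of 19 fatty acid synthesis genes, 13 fell and 2 rose (median -0.24, camera adjusted p = 0.00151, or 0.0664 with an estimated correlation). The fatty acid synthase gene FASN and the desaturase gene FADS2 fell 2.2-fold and 2.59-fold. The lists of cholesterol synthesis (12 higher and 9 lower of 25) and fatty acid oxidation (10 and 6 of 21) were not called, at camera adjusted p-values of 0.88 and 0.939. With median-ratio scaling falls outnumbered rises in both lists, at 11 against 9 and 10 against 7. The sterol isomerase gene EBP fell 3.14-fold, and INSIG1, which holds back sterol synthesis, rose 2.49-fold. PDK4, which diverts pyruvate from oxidation, rose 4.25-fold and ETFB fell 1.85-fold. Of 21 iron and ferroptosis genes, 13 rose and 7 fell (camera adjusted p = 0.874), equal numbers (8 and 8) with median-ratio scaling. The transferrin receptor gene TFRC fell 2.06-fold and SLC3A2 rose 2.75-fold. Of 9 aryl hydrocarbon receptor targets, 5 rose and 3 fell (camera adjusted p = 0.88). CYP1B1 and CYP1A1 rose 3.44-fold and 3.28-fold, and ALDH3A1 and UGT1A6 fell 3.56-fold and 3.7-fold. Of 16 drug metabolism and transport genes, 8 fell and 5 rose (camera adjusted p = 0.0998). With a mean of at least 5 FPKM the list was called lower (median -0.56, camera adjusted p = 0.0343). The bilirubin-conjugating gene UGT1A1 was 15.1-fold lower and the export pump gene ABCC2 2.46-fold. UGT1A1 and UGT1A6 share most of their exons, so their reads cannot be told apart with certainty.

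All 12 tested WNT and beta-catenin target genes fell, with a median log2 change of -0.86 (camera adjusted p = 2.56e-06, or 0.0294 with an estimated correlation). The stem cell receptor gene LGR5 went from 11.2 ± 0.111 to 0.59 ± 0.03 FPKM, AXIN2, a negative-feedback target, fell 6.84-fold, NKD1 7.79-fold and the cyclin D1 gene CCND1 3.45-fold. Of 32 mesenchymal, adhesion and matrix genes, 19 fell (20 adjusted over the list alone) and 8 rose (median -0.43, camera adjusted p = 4.66e-04, or 0.0912 with an estimated correlation). Besides MMP7, the laminin gene LAMB1 fell 7.9-fold and S100A4, a calcium-binding protein linked to metastasis, fell from 4403 ± 126 to 847 ± 27.4 FPKM, while vimentin, VIM, rose 1.76-fold. TGF-beta, SRF and YAP targets went both ways (11 higher and 9 lower of 22, camera adjusted p = 0.874), with 9 higher and 11 lower under median-ratio scaling. The differentiation inhibitors ID1 and ID3 fell 7.14-fold and 6.38-fold, and CCN1 and AJUBA rose 3.85-fold and 3.27-fold. Only 9 of 36 hepatocyte markers reached the expression limit, with 3 lower (2 adjusted over the list alone), 1 higher and no call for the list (camera adjusted p = 0.26). APOH fell 2.25-fold, and SERPINC1 went from 0.107 ± 0.0808 to 2.58 ± 0.21 FPKM. Of 6 biliary and progenitor markers, 5 fell and 1 rose (median -0.73, camera adjusted p = 0.0168, or 0.108 with an estimated correlation). SOX4 fell 2.28-fold and KRT7 rose 3.38-fold. 4 of 16 immune markers were tested and 1 rose (ITGAM, 1.23 ± 0.0945 to 3.13 ± 0.14 FPKM). The macrophage marker CD68 was at 109 ± 4.86 and 99.7 ± 8.32 FPKM (log2 change -0.13 ± 0.061, limma adjusted p = 0.0823), and was called lower with median-ratio scaling (-0.29), with upper-quartile scaling (-0.22) and without the first GK921 library (-0.19). LYZ was at 0.303 ± 0.388 and 2.03 ± 1.69 FPKM (limma adjusted p = 0.0569), and was called higher without the third DMSO library (0.0462) or the second GK921 library (9.34e-04). Of 15 fibroblast and endothelial markers 4 were tested, of which 2 fell and 1, the least abundant over the 6 libraries, rose. LUM fell 1.7-fold, DCN fell from 8.34 ± 0.969 to 0.953 ± 0.196 FPKM, and PECAM1 was at 3.83 ± 0.331 and 3.94 ± 0.8 FPKM (limma adjusted p = 0.888).

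In all, camera called 22 of 35 lists with the preset correlation, 7 higher and 15 lower, and 8 with an estimated one. fry, which asks whether a list moves one way on balance without comparing it with other genes, called 34. The sign of the median and the direction of camera differed for 3 lists, cholesterol synthesis, fatty acid oxidation and TGF-beta, SRF and YAP targets, none of them called.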

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

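The GC and length correction, alone or with the block, the rescaling without the 100 most abundant genes and the shortened MYC target list were chosen after seeing the data. The count of called genes stayed between 8384 and 9181 in all alternatives except a mean of at least 5 FPKM, where 7625 of 9628 tested genes were called, and the treat test against a 1.2-fold change, which by its stricter null called 5730 genes, 3595 higher and 2135 lower. Of the 1864 genes called with a 2-fold change, 1842 or more were still called in the same direction under each other alternative, except 1492 with a mean of at least 5 FPKM, where fewer genes were tested. The count past 2-fold was 1064 with a pseudocount of 5, which shrinks low genes, and 2328 with a pseudocount of 0.1. Leaving out each library gave 8384 to 8474 called genes and 21 to 23 called lists. With the replicate block 8706 genes were called. Deviations of libraries with the same number were only weakly correlated (0.0305, 0.0473 and -0.00207, against -0.0573 to 0.0291 for other pairs). Of the libraries, 4 of 6 correlated best with their own number. These values do not settle whether the numbers pair libraries, so the block was kept as an alternative only. MYC was called higher in each alternative but treat, which was not read for single genes, at 0.22 to 0.42. TGM2 turned to -0.15 with median-ratio scaling (limma adjusted p = 0.00878), -0.074 with upper-quartile scaling (0.121) and -0.085 with quantile normalization (0.0846), against an adjusted p range of 0.00878 to 0.836 over its alternatives. Median ratios and upper quartiles lower every GK921 value against DMSO by construction, and the cause under quantile normalization was not tested. Median ratios also turned SLC30A1 to -0.054, MT-ND1 to -0.014 and PECAM1 to -0.11. PECAM1 was -0.052 with upper quartiles, -0.22 with quantile normalization, and -0.11 to 0.092 over the left-out libraries, never called. Camera called 8 lists with an estimated correlation and fry 34, since fry sets no list against other genes. The direction given by fry was opposite to that of camera for heat shock (median -0.16), cholesterol synthesis (0.12), fatty acid oxidation (0.17), TGF-beta, SRF and YAP targets (0.14) and aryl hydrocarbon receptor targets (0.39). The direction of camera also turned, without a call, for cholesterol synthesis at 5 FPKM (median 0.14) and with quantiles (0.049), and for TGF-beta, SRF and YAP targets with median ratios (-0.018). It turned for H3 lysine 4 methylation genes with median ratios (0.030) and quantiles (0.0097). Over the left-out libraries it turned at least once for those genes (medians 0.16 to 0.20) and for fatty acid oxidation (0.10 to 0.20), and the cause was not tested. The MYC network list was called in 10 of 20 camera alternatives with the preset correlation, at camera adjusted p-values of 0.0241 to 0.0496. These were a pseudocount of 0.1, a mean of at least 5 FPKM, median-ratio, upper-quartile and quantile scaling, the replicate block with and without the GC and length correction, array weights, and the second DMSO or GK921 library left out. At 5 FPKM the drug metabolism and transport list was also called lower (0.0343) and the glycolysis and hypoxia list lost its call (0.0599). Cyclin E1, TUBB6, HTR1D, FOXA2, CD68, SLC30A1 and LYZ lay near the threshold and crossed it in some alternatives. The treat test was run for counts of genes only, not for single genes or lists, and the planned count models were not run because the values are FPKM. Depth sets how finely genes under 1 FPKM are resolved, and its absolute value is unknown.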

Other observations

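Lists of common reference genes, histone variants and histone genes with polyadenylated transcripts were written after values had been seen, and so were the tests of the shortened MYC target list, the genes opposing MYC, both histone explanations and the chromosome 7 genes. Of 16 genes often used to normalise RT-qPCR, 12 fell and 2 rose. GAPDH went from 4968 ± 90.2 to 2075 ± 44.8 FPKM (2.39-fold lower), ACTB from 3172 ± 56.2 to 1914 ± 2.36 and PPIA from 3343 ± 23.8 to 1716 ± 45.9. These 3 were called lower as deposited and under each of the 5 rescalings (GAPDH at -1.43 to -0.98 on the log2 scale). YWHAZ was not called as deposited, at -0.064 ± 0.027. Over the 6 scalings, that of the deposited values included, it lay between -0.23 and 0.012, changed sign, and was called lower under 2.

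Histone genes expressed outside S phase did not follow the replication-dependent ones. Of 9 tested variants, 6 fell and 3 rose. H2AZ1 fell 2.31-fold from 959 ± 16 to 415 ± 29.2 FPKM, H2AX 2.33-fold and H3-3A 2.28-fold. H2AJ rose 1.53-fold.

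Near the MET receptor gene, 4 adjacent genes were abundant in every library. In DMSO, TES was at 682 ± 5.07 FPKM, CAV2 at 9055 ± 48.3, CAV1 at 2961 ± 20.6 and MET at 2289 ± 29, over chromosome 7, 116210493 to 116798386. Of 20168 runs of 4 neighbouring genes, 1, this one, had a lowest member as high (0.00496%). The run was picked because its genes were high, so this rank tests nothing, and the reason for the levels remains open. Genes nearby lay lower, with MDFIC at 293 ± 4.05, TFEC at 1.26 ± 0.304, CAPZA2 at 151 ± 4.57 and ST7 at 6.68 ± 1.01 FPKM.

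The first pattern weighed was the breadth of the response and its tilt towards rises. The real split of the 6 libraries called 8789 genes, and of the 10 splits only this 1 called as many. The highest other split called 0 by limma (46 at an unadjusted p under 0.05, against 8944). Each other split puts both treatments in each group, which widens the spread within groups, so low counts there were fixed in advance. Also, 10 splits are too few for a share under 0.05, so this comparison decides nothing. After a correction for transcript GC content and length 96.3% of the 2-fold calls kept that size and direction, which argues against such a trend as their cause. Without the 100 most abundant genes, which held 33.4% to 33.6% of the FPKM in DMSO and 32.6% to 33.2% after GK921, the median change stayed at 0.16. Whether total RNA per cell changed remains open, because the values are relative.

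The second pattern was the fall of MYC targets beside a rise of MYC mRNA. Without the members shared with the mitosis, replication and nucleotide lists, 41 of 52 targets still fell and 3 rose (median -0.47, camera adjusted p = 2.25e-10). Those shared members therefore did not carry the fall alone. As 52 of 56 tested targets remained, a loss of the call was unlikely from the start. Cell division genes on none of those lists were not removed. Whether the targets fell apart from the cell division genes is thus not decided. Of the rescalings, 0 of 5 ended the call of MYC, which stayed at 0.22 to 0.40, or of its targets. All 5 were relative and moved values little, so a scaling to RNA per cell, which was not measured, remains open. Genes that oppose MYC in the MAX network had a median log2 change of 0.88, at percentile 98.9 of 10000 random lists of 6 matched on expression, with 5 higher and 1 (MXD3) lower. These genes were picked after the rise of the network had been seen, so the percentile restates that rise, and whether they hold MYC targets down remains open, as does slower growth (MYC protein, its binding to DNA and histone serotonylation were not measured).

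The third pattern was the rise of replication-dependent histone transcripts while S-phase genes fell. Over a wider set of 29 such genes, 25 rose and 1 fell (H2AC20). More RNA without a poly(A) tail in the treated libraries would raise all of them, and the 3.45% that fell is 1 gene, too few to exclude it, so it cannot be told apart from a change in the cells. H2BC21, H2AC6, H2BC4, H1-2 and H2BC12 are known to give polyadenylated transcripts in non-dividing cells. These 5 genes rose by a median of 2.85, against 1.96 for the others, a difference of 0.90 (exact one-sided permutation p = 0.0151). That list was written after some of these values had been seen, so the p does not decide whether polyadenylated histone transcripts add to the rise, and reads shared between these similar genes remain untested.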
